A study of Mus musculus with 6 samples.

How the data were processed

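Gene expression was measured in whole testes of 3 AROM+ and 3 WT mice, 1 testis per array, on one-colour Agilent arrays with Cy3. The samples were grouped by genotype from their labels, which name single testes. The limma p-values of genes measure the spread between these testes, and those of camera also set a list against the other genes. The p-values of regions count features, 1 per gene or locus name of the probes. The spot intensities were deposited as scanner output of Agilent Feature Extraction, version 10.7.3.1 per the file headers and 10.10 per the submitters' processing notes. The processed signal is a background-corrected intensity per the file headers. A table of log2 values was also deposited by the authors, and its scale was found by comparison: each column equals log2 of the processed signal minus 1 constant per array (slope 1.00), and genes were not centred. Its column medians were −3.12, −3.11 and −3.09 in WT and −3.05, −3.09 and −3.02 in AROM+. All 6 arrays lie on 1 slide, with WT in one row of the slide and AROM+ in the other, so slide position and group cannot be told apart. No spot was saturated. The number of arrays limits the precision.

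For the main analysis, log2 of the processed signal minus each array's 75th percentile was used. Each array had 62976 spots, of which 3671 were control spots and were left out, as were spots with outlier flags (123 to 192 per array). Spots of one probe were averaged, giving 55681 probes. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 42636. Probes were named through the RefSeq table of GRCm38.p6, used for names only: 26068 by accession, 3814 by symbol and 637 by a synonym of 1 gene. The 702 probes that list several genes and 24460 with no match were not named. A gene was represented by its kept probe of highest mean over the 6 arrays, and 18850 genes were tested. Probe coordinates are those of the files (NCBI37/mm9).

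Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. A gene well above background on every array of one group, and by none of its probes on any array of the other, has only a bound. Its fold was computed against a floor on each array of the dim group, the lowest value of a probe well above background or the probe's own value if higher. The 31 gene lists hold 477 genes, of which 469 have a probe. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists: 15 were called up and 3 down. With an estimated correlation 0 of the 31 were called.

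The named genes were set by a rule fixed, like the lists and the first set of other settings below, before the data were examined: Cyp19a1, the 8 largest rises and 8 largest falls among called genes measured on all arrays without overlap of the groups, the 4 largest bounds in each direction, up to 4 called members of each list (or the member with the smallest p), and a fixed set that includes Esr1, Lhcgr, Star, Cyp17a1, Hsd17b3 and Insl3. Clone and predicted gene names were passed over for the largest changes and bounds. Some genes that the rule names are not reported here.

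The fit was tested on simulated data for the AROM+ against WT comparison, with 18850 genes of which 200 were changed. It recovered 14% of genes changed by 0.5 on the log2 scale, 68% of those changed by 1, 96% of those changed by 2 and 98% of those changed by 4, with 7 false calls among 145. Far more genes were called in the data than were changed in the simulation, so these shares do not give the power of the real comparison. Other settings tried were normexp background correction (offset 50), quantile normalization, scaling to the median of bright probes, the deposited log2 table, no filter on dim probes, a filter requiring all 6 arrays, the mean of a gene's probes, the replicate number as a block, eBayes with a trend, array weights, camera with an estimated correlation, and leaving out each array. Spike-in scaling, centring on the gene median, and keeping probes that list several genes were added after seeing the data.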

Results

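The series measured messenger RNA in whole testes of male mice at 5 months of age. One group of 3 carried a transgene that over-expresses aromatase, the enzyme that turns androgens into oestrogens, and is called AROM+ here. The other group of 3 was wild type (WT). The labels give the C57BL/6 background for both. Each testis was hybridised to 1 one-colour Agilent array, and the comparison asks which transcripts differ between AROM+ and WT testes. Between 76.6% and 80.6% of the spots on an array were well above background, and the 75th percentile of the processed intensity lay between 3696 and 5431. Arrays of one group correlated more closely across genes (r = 0.994 to 0.996 within WT, 0.986 to 0.991 within AROM+) than arrays of different groups (r = 0.949 to 0.979). Genes are not independent replicates. Values below are log2 differences, AROM+ minus WT, with their standard error (SE) from limma, over 3 arrays per group.

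Endogenous Cyp19a1, the mouse aromatase gene, was not called different. Its probe (A_51_P474551, chromosome 9, 54013778 to 54013837, NCBI37/mm9) read −2.91 ± 0.32 in WT and −3.21 ± 0.20 in AROM+ (log2 intensity relative to the array's 75th percentile, SD, n = 3), a difference of −0.30 ± 0.18 (limma, adjusted p = 0.208). With normexp background correction the fall was −0.42 and passed the threshold (adjusted p = 0.0158), and it also passed without WT replicate 2 (−0.48). The labels do not say which species' sequence the transgene carries, so this probe may not detect it and does not check the genotype labels.

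Most macrophage and matrix genes of the lists and several steroid pathway genes were higher in AROM+ testes, and most spermatid genes were lower by smaller amounts. Of 18850 genes tested with limma, 3747 were higher and 6142 lower at an adjusted p under 0.05. The lower count was 3936 without WT replicate 1 and 3817 without WT replicate 3. The balance moved with the scaling, from 3912 higher and 4284 lower with quantile normalization to 3151 and 7814 with centring on the gene median, and 2420 and 4162 with spike-in scaling. By size the order turned: 1292 genes were at least 2-fold higher and 249 at least 2-fold lower (116 with normexp background correction, 408 with centring on the gene median). The median difference over all genes was −0.14, so many of the small falls lie near the shift of the whole distribution, and the relative medians below are list medians minus it. In 63.5% of genes the values of the groups did not overlap, against 10% by chance, and 11279 genes had an unadjusted p under 0.05. In 208 called genes, different probes of the gene were called in opposite directions.

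Among genes measured on all 6 arrays, Clec4d, a C-type lectin of myeloid cells, had the largest rise of a brightest probe among the named genes, 6.28 ± 0.56 (77.7-fold, adjusted p = 0.00188). With the mean of a gene's probes Atp6v0d2 was at 6.72. Tcaf1 (5.34 ± 0.66), Mmrn1 (5.12 ± 0.37), the chemokine gene Ccl6 (5.06 ± 0.35), Heph (4.93 ± 0.48), the stress-induced transcription factor Atf3 (4.73 ± 0.41) and the acute-phase gene Saa3 (4.72 ± 0.41) also rose. The probes of Tcaf1 ranged from 1.25 to 5.34 and those of Heph from 0.69 to 5.46. Hsd3b2, of the 3β-hydroxysteroid dehydrogenase family, fell by 4.18 ± 0.51 on the log2 scale (adjusted p = 0.00299), and Hsd3b3 fell by 3.14 ± 0.79. Paralogs of this family are close in sequence, so their probes may share signal. Aldh3a1 (−2.77 ± 0.20), Bhmt (−2.67 ± 0.13), Cstdc2 (−2.45 ± 0.64), Ccl28 (−2.15 ± 0.63), Ttc9b (−2.01 ± 0.36) and Tbx19 (−1.93 ± 0.24) were lower. The calls of Hsd3b3, Cstdc2 and Ccl28 were lost without WT replicate 1, those of Cstdc2 and Ccl28 also without WT replicate 3, and that of Ccl28 also without AROM+ replicate 1 or 2.

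Some genes were well above background in one group only, and their fold is a lower bound under the main background handling. With normexp background correction, which adds an offset, fitted changes lay under these bounds, for Sfrp4 at 6.62, Gpnmb at 6.47, Mmp12 at 4.91, H2-Ea at 4.62, Ren1 at −1.87, Slc23a1 at −0.71, Olfr116 at −0.85 and Pax6 at −0.92, all past the threshold. So did those of C5ar1 (2.42), Il1a (0.45), Ret (0.59) and H2-DMb2 (0.64), named further on, of which H2-DMb2 lost its call. In AROM+ these were 68 genes, led by the Wnt modulator Sfrp4 (at least 254-fold higher, adjusted p = 0.00166), Gpnmb (at least 195-fold), the macrophage metalloprotease Mmp12 (at least 78.0-fold) and H2-Ea (at least 55.0-fold). H2-Ea is measured by a probe on chromosome 17 (34481469 to 34481528, mm9). In WT these were 59 genes, of which 54 were called lower, led by the renin gene Ren1 (at least 6.82-fold lower, adjusted p = 0.00175), Slc23a1 (at least 2.61-fold), Olfr116 (at least 2.49-fold) and Pax6 (at least 2.39-fold).

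Macrophage genes rose together. In the list of lipid-laden and multinucleated macrophages, 14 of 17 measured genes were higher and 0 lower (median 2.15, relative median 2.29), among them Gpnmb, Mmp12, the proton pump gene Atp6v0d2 (4.98 ± 0.34) and osteopontin, Spp1 (4.05 ± 0.41). Of 20 general macrophage genes 16 were higher and 1 lower (median 1.82, relative median 1.97), with Lyz2 at 2.79 ± 0.37, Tyrobp at 2.68 ± 0.27, Cd68 at 2.40 ± 0.28 and the protease gene Ctss at 2.32 ± 0.22. The camera test called both lists up (adjusted p = 7.55e-10 and 3.05e-07). With an estimated correlation neither held (adjusted p = 0.429 for both). With p adjusted over the list alone, 14 and 16 genes were higher, with 1 of the general macrophage genes lower.

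The complement, chemokine, interferon and class II lists were also called up by camera at the preset correlation. Of 11 complement genes 9 were higher (relative median 1.54), with the receptor genes C3ar1 at 3.22 ± 0.36 and C5ar1, seen in AROM+ only, at least 8.71-fold higher, and Cfb at 2.50 ± 0.39 (camera adjusted p = 1.72e-06). Of 15 cytokine and chemokine genes 7 were higher (median 1.42, or 1.27 with 1 gene at its bound, relative median 1.56), led by Ccl3 (4.33 ± 0.42), Ccl4 (2.24 ± 0.50), Cxcl1 (1.74 ± 0.27) and, in AROM+ only, Il1a at least 2.42-fold (camera adjusted p = 0.000745). Both lost the call with an estimated correlation (adjusted p = 0.429). Of 16 interferon-stimulated genes 7 were higher and 2 lower (relative median 1.07), with Oas1a at 2.27 ± 0.46, Rsad2 at 1.97 ± 0.44, Bst2 at 1.37 ± 0.30 and Ifit3 at 1.23 ± 0.35 (camera adjusted p = 0.00479, and adjusted p = 0.593 with an estimated correlation). Without WT replicate 1, 3 interferon-stimulated genes were higher. Of 11 genes for MHC class II presentation 6 were higher, among them H2-Ea, Cd74 (1.46 ± 0.34), H2-Eb1 (1.63 ± 0.47) and, in AROM+ only, H2-DMb2 at least 1.85-fold (camera adjusted p = 0.00212, and adjusted p = 0.502 with an estimated correlation). The class II median was 1.04 (relative median 1.19), or 1.00 with the genes seen in one group only at their bound. Adjusted over the list alone, 10, 7, 8 and 6 genes of these lists were higher and 2 interferon-stimulated genes were lower.

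Matrix and vessel genes rose. Of 20 extracellular matrix genes 15 were higher and 0 lower, with the protease inhibitor Timp1 at 3.47 ± 0.29, Lum at 3.27 ± 0.45, Mmp2 at 2.91 ± 0.36 and the collagen gene Col3a1 at 1.98 ± 0.23 (camera adjusted p = 3.05e-07). The matrix median was 1.34 (relative median 1.49), or 1.21 with 1 gene at its bound. Of 12 endothelial genes 9 were higher and 1 lower (relative median 1.14), with Plvap at 1.96 ± 0.30 (its other probe, not called, at 0.47), Tie1 at 1.65 ± 0.29, Pecam1 at 1.45 ± 0.31 and Emcn at 1.45 ± 0.31 (camera adjusted p = 0.00027). Neither call held with an estimated correlation (adjusted p = 0.429 for both). The counts adjusted over the list alone were 16 matrix genes higher, and 9 endothelial genes higher and 1 lower.

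Steroid genes changed in both directions. Of 18 steroidogenic genes 9 were higher and 1 lower (median 0.62, relative median 0.77), with Akr1c14 at 3.76 ± 0.27, the side-chain cleavage enzyme Cyp11a1 at 1.75 ± 0.37, Srd5a1 at 1.47 ± 0.19 and Hsd3b1 at 1.30 ± 0.19 (camera adjusted p = 0.000642). Star, the cholesterol transfer protein, was at −0.40 ± 0.62 (adjusted p = 0.612), Cyp17a1 at −0.42 ± 0.36 (adjusted p = 0.358) and Hsd17b3, which makes testosterone, at −1.08 ± 0.78 (adjusted p = 0.277). None of these 3 passed the test, and over the settings Star ran from −1.02 to 0.0111, Cyp17a1 from −0.78 to −0.19 and Hsd17b3 from −1.75 to −0.09. Of 15 Leydig cell markers outside the steroid pathway 8 were higher and 1 lower (relative median 0.73), led by the luteinising hormone receptor gene Lhcgr (3.72 ± 0.96, adjusted p = 0.0181), Tcf21 (1.42 ± 0.27), the prolactin receptor gene Prlr (1.38 ± 0.25) and Nr2f2 (1.20 ± 0.13), with a camera adjusted p of 0.0143. The Lhcgr call was lost without WT replicate 1, WT replicate 3 or AROM+ replicate 2, and 3 Leydig cell markers were called higher without WT replicate 1 or 3. Both lists lost the call with an estimated correlation (adjusted p = 0.429). Insl3 had no probe of its own and is not among the 15 markers counted. The probe that lists Insl3 and Jak3 was at −2.10 ± 0.74 (limma, adjusted p = 0.0568). In WT it read 5.11, against −0.75 for a probe of Jak3 alone, whose difference was −0.39 ± 0.11. Most of the signal of the shared probe may therefore come from Insl3. Of 11 genes of oestrogen and androgen conversion 5 were higher and 1 lower (relative median 0.57), with Hsd17b11 at 2.18 ± 0.25, Cyp1b1 at 1.80 ± 0.16, Sult1a1 at 1.48 ± 0.14 and Hsd17b2 at −0.80 ± 0.10, and the list was not called (camera adjusted p = 0.0587). Of these 11 genes 3 were higher without WT replicate 1, WT replicate 3 or AROM+ replicate 1. Another probe of Srd5a1 was at −0.32. Adjusted over the list alone, 10, 8 and 5 genes of these lists were higher and 1 of each was lower.

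Of 15 oestrogen-responsive genes 10 were higher and 0 lower (relative median 1.17), with C3 at 3.095 ± 0.396, Myc at 2.76 ± 0.32, Greb1 at 2.51 ± 0.26 and Ctsd at 1.36 ± 0.16 (camera adjusted p = 2.38e-05, and adjusted p = 0.429 with an estimated correlation). C3, Myc and Ctsd are also expressed by immune cells. Of 14 nuclear and sex steroid receptor genes 4 were higher and 5 lower (relative median −0.02), and the list was not called (camera adjusted p = 0.805). The number of receptor genes lower was 3 without any 1 of the arrays other than AROM+ replicate 2. The oestrogen receptor gene Esr1 was at 1.38 ± 0.36 (adjusted p = 0.0186) by its brightest probe, at 0.97 ± 0.30 by another and at −0.60 ± 0.16 by the last, and the mean of its probes was not called (0.58, adjusted p = 0.0574). The Esr1 call was also lost without WT replicate 1, WT replicate 3 or AROM+ replicate 2. Nr0b2 rose by 0.90 ± 0.19 and Nr3c1 by 0.70 ± 0.11, with its other probe, not called, at 0.02. Of 21 sterol synthesis and uptake genes 7 were higher and 0 lower (relative median 0.45), with Srebf2 at 2.37 ± 0.36 (its other probe at 0.63), Sc5d at 1.78 ± 0.42 and Msmo1 at 1.09 ± 0.20 (camera adjusted p = 0.00888, and adjusted p = 0.593 with an estimated correlation). The sterol count was 4 higher without WT replicate 1, WT replicate 3 or AROM+ replicate 2, the last with 2 lower, and 12 higher without AROM+ replicate 3. Adjusted over the list alone, 11, 4 and 4 genes of these lists were higher, and 5 receptor genes were lower.

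Most genes of the germ cell lists after the spermatogonial stage were called lower in the main analysis. All 20 round spermatid genes were called lower (median −0.43, relative median −0.28), with the sperm surface gene Spam1 at −0.70 ± 0.18, Catsper3 at −0.77 ± 0.18, Izumo1 at −0.63 ± 0.11 and Zpbp at −0.54 ± 0.09. Of 20 elongating spermatid genes 13 were lower and 0 higher (median −0.38, relative median −0.23), with Akap4 at −0.56 ± 0.14, Oaz3 at −0.56 ± 0.08, Fscn3 at −0.55 ± 0.10 and Cabs1 at −0.46 ± 0.10. Of 30 meiotic genes 17 were lower and 1 higher (median −0.33, relative median −0.19), with Spo11, which cuts DNA in meiosis, at −0.95 ± 0.15, Ccna1 at −0.69 ± 0.09, Ddx4 at −0.51 ± 0.15 and Adam2 at −0.49 ± 0.07. Camera called the 3 lists down (adjusted p = 6.61e-05, 0.00104 and 0.0143), and none held with an estimated correlation (adjusted p = 0.429, 0.429 and 0.552). With quantile normalization the elongating spermatid and meiotic lists were not called (adjusted p = 0.0637 and 0.0754), and 5 round, 2 elongating and 5 meiotic genes of the lists were called lower. With that scaling Akap4 was at −0.33 (adjusted p = 0.0552), Cabs1 at −0.24 (adjusted p = 0.117) and Ddx4 at −0.33 (adjusted p = 0.122). With spike-in scaling 13 round, 7 elongating and 8 meiotic genes were called lower. Without WT replicate 1 and without WT replicate 3, 13 round spermatid genes were called lower, and 8 and 9 meiotic genes. The meiotic count was 11 without WT replicate 2 and 9 without AROM+ replicate 1. Adjusted over the list alone, 20, 15 and 18 genes were lower and 1 meiotic gene was higher. The macrophage and matrix lists above moved the other way in the same testes.

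**Figure D1:**
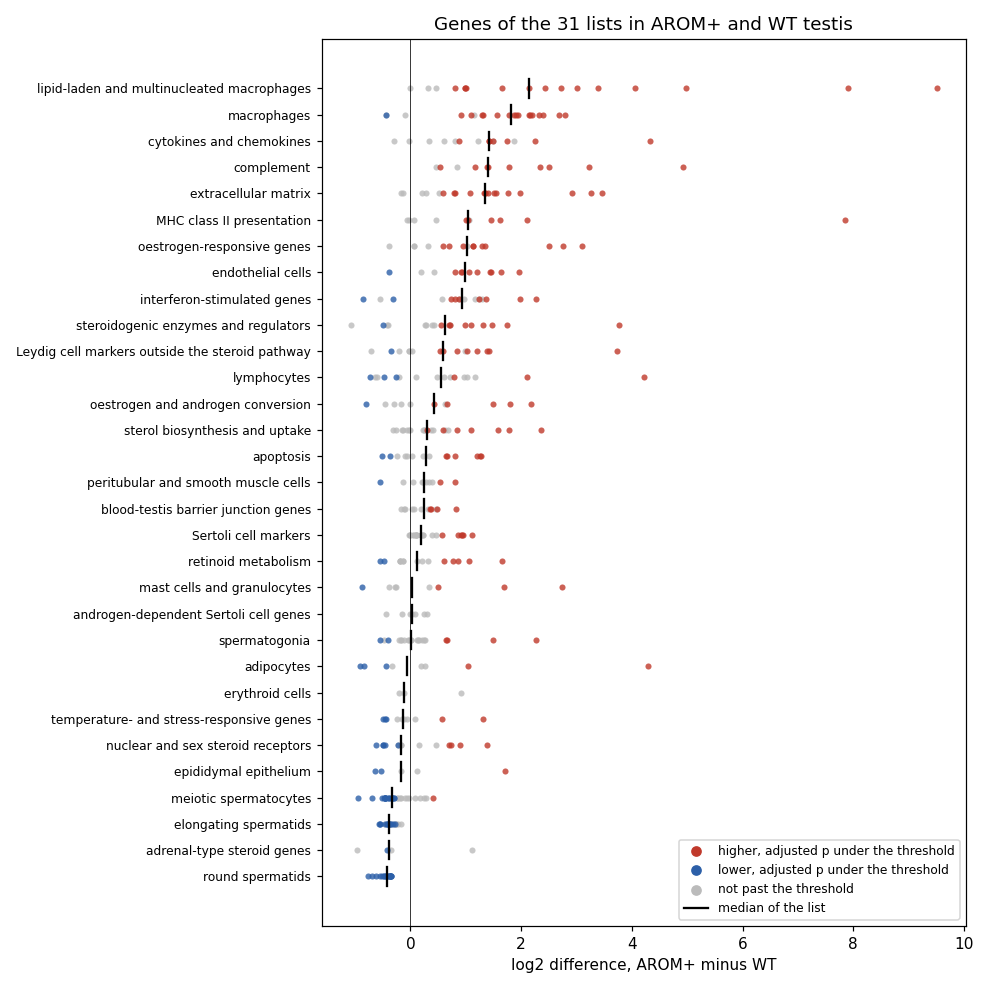
Log2 difference (AROM+ minus WT, horizontal axis) of each measured gene of the 31 lists, 1 point per gene, red for called higher, blue for called lower and grey for not past the threshold, with a black bar at the list's median. Fitted values are drawn, also for genes seen in one group only; the macrophage medians lie at 1.82 and 2.15 and the round spermatid median at −0.43.

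Sertoli cell and junction genes rose as lists, and spermatogonial, androgen-dependent and peritubular lists were not called. Of 21 spermatogonial genes 4 were higher and 2 lower (relative median 0.16), with Kit at 1.48 ± 0.28, Foxo1 at 0.66 ± 0.13, Zbtb16 at 0.65 ± 0.16 and, in AROM+ only, Ret at least 2.10-fold, and the list was not called (camera adjusted p = 0.223). Without AROM+ replicate 1, 7 spermatogonial genes were higher. Kit is also expressed by Leydig and mast cells. Of 21 Sertoli cell markers 6 were higher and 0 lower (relative median 0.34), with Kitl at 1.10 ± 0.18, Inha at 0.94 ± 0.18, Gata4 at 0.93 ± 0.14 and Trf at 0.91 ± 0.13 (camera adjusted p = 0.00215). Of 12 blood-testis barrier junction genes 4 were higher (relative median 0.40), with the gap junction gene Gja1 at 0.82 ± 0.09, F11r at 0.48 ± 0.10, Cldn5 at 0.38 ± 0.10 and Ctnnb1 at 0.35 ± 0.09 (camera adjusted p = 0.0295, and adjusted p = 0.0647 without AROM+ replicate 3). Without WT replicate 1 or 3, 2 junction genes were higher, and 1 with spike-in scaling. Both lists lost the call with an estimated correlation (adjusted p = 0.527). Of 7 androgen-dependent Sertoli cell genes 0 passed the limma test, and Tubb3 was closest (0.30 ± 0.12, adjusted p = 0.0663; relative list median 0.16, camera adjusted p = 0.648). Of 10 peritubular and smooth muscle genes 2 were higher (1 without WT replicate 1, WT replicate 3, AROM+ replicate 1 or AROM+ replicate 3) and 1 lower (relative median 0.40), with Smtn at 0.81 ± 0.21, Lmod1 at 0.53 ± 0.16 and Actg2 at −0.54 ± 0.09 (camera adjusted p = 0.0922). When adjusted over the list alone, 4 spermatogonial, 4 Sertoli, 4 junction and 1 peritubular genes were higher, and 2 spermatogonial and 1 peritubular genes lower.

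**Figure D2:**
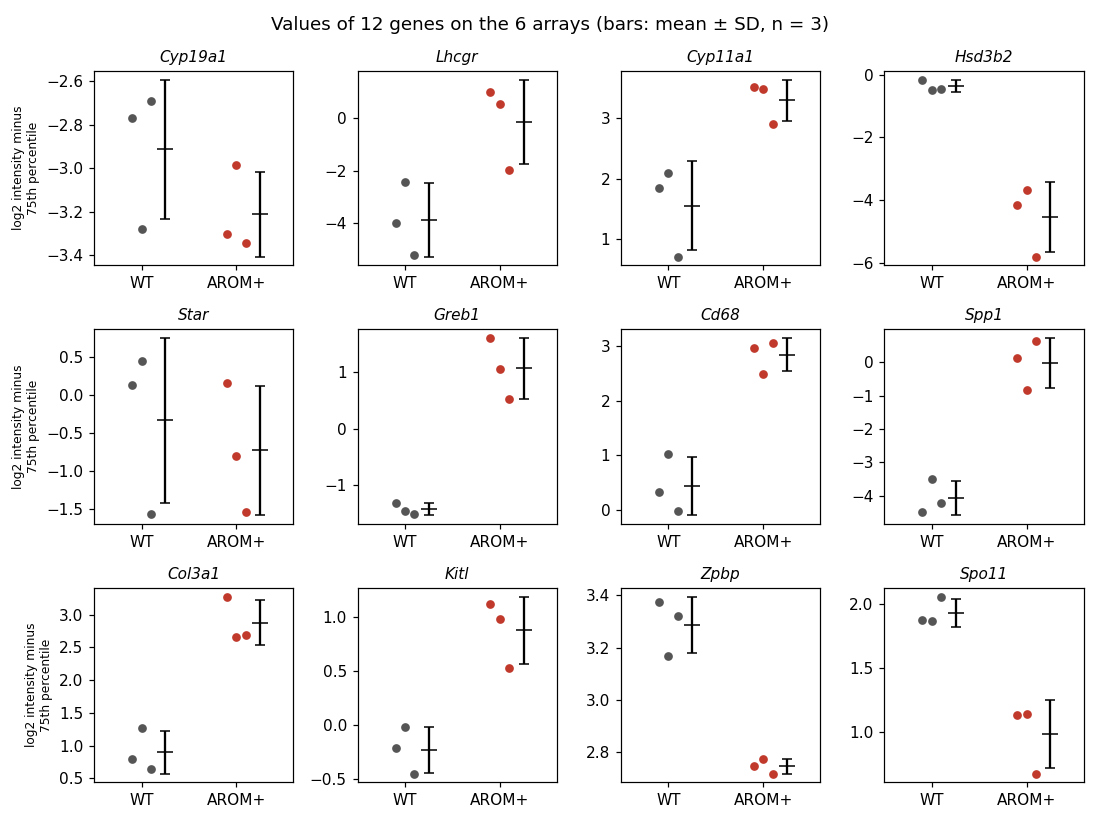
Log2 processed intensity minus the array's 75th percentile (vertical axis, its range set for each panel) of 12 genes, 1 point per array, with mean and SD (n = 3) beside the points. Cyp19a1 and Star overlap between the groups, and the other 10 genes do not.

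Of 14 apoptosis genes 6 were higher and 2 lower (relative median 0.43), with Casp8 at 1.27 ± 0.21, Fas at 1.25 ± 0.16, Cdkn1a at 1.20 ± 0.14 (another of its 3 probes, not called, at −0.0014) and Bax at 0.80 ± 0.25 (camera adjusted p = 0.0437). This call was lost without WT replicate 1 (adjusted p = 0.0538), AROM+ replicate 1 (adjusted p = 0.0951) or AROM+ replicate 3 (adjusted p = 0.0549), with quantile normalization (adjusted p = 0.0817), with the mean of a gene's probes (adjusted p = 0.0548) and with an estimated correlation (adjusted p = 0.429). The number of apoptosis genes lower was 0 without WT replicate 1, WT replicate 3 or AROM+ replicate 2, and 1 without AROM+ replicate 1 or 3. The remaining lists were not called by camera. Of 16 lymphocyte genes 3 were higher and 3 lower (relative median 0.69), with Il7r at 4.22 ± 0.49 (well above background on 2 of 3 WT arrays), Cd79b at 2.10 ± 0.32, Cd4 at 0.79 ± 0.18 and Cd3d at −0.72 ± 0.19 (adjusted p = 0.142, and adjusted p = 0.0465 with 7 genes higher without AROM+ replicate 2). The other probe of Cd4 was at −0.28, the mean of its probes was not called (0.26, adjusted p = 0.0751), and its call was lost with spike-in scaling (adjusted p = 0.0534). The number of lymphocyte genes lower was 1 without WT replicate 1 and 0 without WT replicate 2 or 3. Of 8 mast cell and granulocyte genes 3 were higher and 1 lower (relative median 0.18), with S100a8 at 2.73 ± 0.68 (well above background on 1 of 3 WT arrays, range over settings 1.28 to 3.41), S100a9 at 1.69 ± 0.55, Hdc at 0.50 ± 0.13 and Mpo at −0.87 ± 0.08 (adjusted p = 0.508). Of these 8 genes 0 were higher without WT replicate 1 and 1 without WT replicate 2. Of 15 retinoid genes 5 were higher and 2 lower (1 without any 1 of the arrays but WT replicate 3, relative median 0.26), with Dhrs3 at 1.66 ± 0.14, Aldh1a3 at 1.06 ± 0.15 and Rdh10 at 0.86 ± 0.14 (adjusted p = 0.125). Of 10 temperature and stress genes 2 were higher and 3 lower (relative median 0.014), with Hmox1 at 1.31 ± 0.23, Rbm3 at 0.57 ± 0.10, Hsph1 at −0.49 ± 0.11 (its other probe, not called, at −0.17) and Ddit3 at −0.45 ± 0.09 (adjusted p = 0.805). Another probe of Rbm3 was at −0.33. Of 8 adipocyte genes 2 were higher (1 without WT replicate 1 or 3) and 3 lower (relative median 0.08), with Fabp4, which macrophages also express, at 4.29 ± 0.42, Plin1 at 1.04 ± 0.27, Cidec at −0.91 ± 0.18 (well above background on 1 of 3 AROM+ arrays) and Retn at −0.84 ± 0.12 (adjusted p = 0.817). Of 5 epididymal genes 1 was higher and 2 lower (relative median −0.03), with Cst11 at 1.71 ± 0.54, Lcn9 at −0.65 ± 0.15 (well above background on 1 of 3 AROM+ arrays) and Rnase10 at −0.53 ± 0.10 (adjusted p = 0.805). Of 4 adrenal-type steroid genes 1, Cyp11b2, was lower at −0.42 ± 0.10 (relative median −0.24, adjusted p = 0.773), and of 3 erythroid genes 0 passed the limma test, with Hbb-bt at 0.91 ± 0.45 (relative median 0.03, camera adjusted p = 0.773). Adjusted over the list alone, the numbers of genes higher and lower in these 8 lists were as over all genes tested, and those of the apoptosis list too.

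Some named genes lost their call when 1 array was left out. Without WT replicate 1 the calls of Spam1, Ddx4, Zbtb16, Bax, H2-Eb1, H2-DMb2, Ifit3, S100a8, S100a9, Hdc, Cst11, Plin1, Lmod1, Cldn5 and Ctnnb1 were lost. Without WT replicate 3 those of Spam1, Ddx4, Zbtb16, Bax, H2-Eb1, Cd3d, S100a9, Cst11, Plin1, Hsph1, Lmod1, Cldn5 and Ctnnb1 were lost, and without WT replicate 2 those of Ddx4, H2-Eb1, H2-DMb2, Ifit3, Cd3d, S100a9, Hdc, Cst11 and Lmod1. Bax was also lost without any 1 of the AROM+ replicates, Cst11 without AROM+ replicate 1 or 2, Ddx4 and S100a9 without AROM+ replicate 1, Spam1 without AROM+ replicate 3, and Lmod1 without AROM+ replicate 1 or 3.

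Other settings also ended or added calls of named genes. With quantile normalization the calls of Akap4, Cabs1, Ddx4, Ddit3 and Lcn9 were lost and Tubb3 was called higher (adjusted p = 0.0436). With spike-in scaling those of Ddx4, Cd4, Cldn5, Ctnnb1, F11r, Hdc and Rbm3 were lost, and with normexp background correction those of F11r, H2-DMb2, Lmod1 and S100a9. Lmod1 was also lost with median scaling, with centring on the gene median, as was Ctnnb1, and with a variance trend, which called Tubb3 higher (adjusted p = 0.0450). Cst11 and S100a9 were lost with no filter on dim probes, and Hsph1, like Cd4 and Esr1, with the mean of a gene's probes. With array weights Hbb-bt was called higher (1.22, adjusted p = 0.0440).

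Leaving out 1 array also moved some small member counts of lists. Macrophage genes lower were 0 without WT replicate 1, WT replicate 2 or AROM+ replicate 2, and 2 without AROM+ replicate 1. Leydig cell markers lower were 2 without AROM+ replicate 3, 1 without AROM+ replicate 2 and 0 without any 1 of the others. Interferon-stimulated genes lower were 1 without any 1 of the WT arrays or AROM+ replicate 2, and conversion genes lower were 2 without WT replicate 2. Meiotic genes higher were 0 without any 1 of the arrays but AROM+ replicate 1, and epididymal genes higher were 0 without any 1 of the WT arrays or AROM+ replicate 2. Adrenal-type genes lower were 2 without WT replicate 2. Without AROM+ replicate 3, 1 adrenal-type gene was higher and 1 androgen-dependent Sertoli cell gene lower, and without WT replicate 3, 1 cytokine gene was lower.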

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

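Of the tests below, those of the MHC region, of macrophage genes and of dilution, and the count of single round spermatid genes under other scalings, were chosen only after the results were seen. The splits of the samples were planned, as was the test of the germ cell lists, except for 2 of its 6 scalings, spike-in scaling and centring on the gene median.

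A signal appears in probes with no single named gene, which the comparison of genes does not use. Of 16296 such probes tested with limma, 1034 were higher and 4393 lower in AROM+ at an adjusted p under 0.05, and 322 and 269 of these by at least 2-fold. No explanation was tested for them.

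The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes higher the real split gave 3747 calls and the highest other split 0, so 1 of 10 splits gave as many. For genes lower the values were 6142 and 0 (1 of 10), for genes at least 2-fold higher 1292 and 0 (1 of 10), and for genes at least 2-fold lower 249 and 0 (1 of 10). For lists called by camera the real split gave 18 and the highest other also 18, so 2 of 10 splits gave as many. That other split set WT 1, WT 2 and AROM+ 3 against the rest, and the remaining 8 splits called 6 to 16 lists. Each of the other splits still sets 2 animals of one genotype with 1 of the other against the reverse, so a genotype difference remains in it. On simulated data camera called 0 of 30 unshifted lists. The simulated genes were independent of each other, so this does not check lists of correlated genes.

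Lower spermatid and spermatocyte genes may be due in part to array scaling. All 3 lists stayed down by camera under 5 of 6 other scalings, and under quantile normalization 2 of them were not called. Median scaling, the deposited table, spike-in scaling and gene-median centring shift all genes of an array alike. Camera sets a list against the other genes, so these settings could change its result only a little. Calls near the threshold did move, such as that of the junction genes (camera adjusted p = 0.0573 with spike-in scaling). Under quantile normalization 5 of the 20 round spermatid genes were called lower, the fewest of the 6 scalings. Dilution of all germ cell RNA alike by other RNA stays open. The spermatogonial median lay above the round spermatid median by 0.444 (95% bootstrap interval over genes 0.297 to 0.647). However, 4 of the 21 spermatogonial genes were higher and 2 lower, and Kit is also expressed by Leydig and mast cells. RNA added by other cells may lift this list, so the difference decides nothing. An effect of the genotype stays open, and slide position follows the genotype.

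Higher macrophage genes were set against other sources of RNA, and no test excludes any of the 3. The difference in medians, macrophage minus epididymal, was 2.00 (95% interval 0.07 to 2.59), over 5 epididymal genes of which 1 rose and 2 fell, and of the seminal vesicle genes Svs5 (3.18) and Svs6 (4.59) rose and Svs4 (−1.004) fell. The difference from lymphocyte genes was 1.28 (0.52 to 2.20), but 3 of these rose, Il7r by 4.22 and Cd79b by 2.10, 3 fell, and expression in other cells may hide a small share. More blood in the AROM+ testes stays open, since the difference of 1.94 (0.40 to 2.27) rests on 3 erythroid genes. Hbb-bt was called higher with array weights and with the replicate block. Probes that list both Hba-a1 and Hba-a2 were at 0.62 and 0.57 and were not called (limma, adjusted p = 0.106 and 0.194). More macrophages, or higher expression in each, may both underlie the pattern and were not told apart.

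H2-Ea was seen in AROM+ only, and C57BL/6 mice are known to carry a deletion in this gene's promoter, so a different MHC haplotype in the AROM+ animals may account for it. All-or-none signals were 6 of 216 features in the MHC region (2.78%) and 422 of 28463 elsewhere (1.48%), an odds ratio of 1.90 (95% interval 0.685 to 4.24, Fisher's p = 0.144). The 6 include H2-Ea itself, the gene to be explained, and H2-Ob, since any 1 all-or-none probe sufficed to count a feature. Of the 6, 5 counted as seen in AROM+ only and 1, Olfr116, in WT only. An interval that includes 1 was written down as counting against this explanation. The interval also covers ratios well above 1, so the count of signals decides nothing. A different haplotype would follow the genotype here, so its effects and those of the transgene could not be told apart. More immune cells of the same haplotype were also weighed. In WT, H2-Eb1 (−0.85, SD 0.20) and Cd74 (1.13, SD 0.21) were well above background on all 3 arrays, and H2-Ea (−8.95, SD 0.05) was not on any. By brightest probes the 10 other class II genes had a median rise of 1.02 and a largest of 2.10, against at least 5.78 for H2-Ea. For H2-Ea, these values argue against more such cells alone. The bound for H2-Ea exceeded the largest rise of any other class II probe by only 0.33 log2. That probe, one of H2-Ob, was itself seen in AROM+ only, so its rise is a fitted value and this difference decides nothing. The brightest H2-Ob probe rose by 1.005. Comparisons run earlier gave 4.15 (half-widths 2.58) against 6 chosen class II genes and 3.68 (half-widths 2.89) against the brightest probe of each, the largest of which, of H2-DMb2, is again a fitted value.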

How the results depend on the processing

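Spike-in scaling, centring on the gene median and keeping probes that list several genes were chosen only after the results were seen; the other alternatives were planned. Of the values of single genes over all alternatives, 2489 kept direction and side of the threshold, 91 lost the call, 6 gained one and 1 reversed; of the list results 577, 29, 5 and 9. Of the numbers of list members higher or lower, 1028 stayed within 1.5 times and 150 did not. No reversed value was past the threshold on either side. The cause was not tested. The median over all genes ran from −0.06 (quantile normalization) to −0.24 (centring on the gene median).

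Genes at least 2-fold lower were 116 with normexp background correction and 408 with gene-median centring, and genes higher were 2420 with spike-in scaling. Cyp19a1 was at −0.42 with normexp (adjusted p = 0.0158, range over alternatives 0.0158 to 0.476). With quantile normalization the adjusted p was 0.0817 for apoptosis, 0.0637 for elongating spermatids and 0.0754 for meiotic spermatocytes, and temperature- and stress-responsive genes reversed (0.517). Oestrogen and androgen conversion gained a call with median scaling (0.0425), no filter on dim probes (0.0305), spike-in scaling (0.0439) and gene-median centring (0.0393). With no filter, adipocytes (0.935), adrenal-type steroid genes (0.661), epididymal epithelium (0.928) and erythroid cells (0.935) reversed. Epididymal epithelium also reversed with probes above background on all arrays (0.853), and temperature- and stress-responsive genes with multi-gene probes kept (0.868). Apoptosis lost its call with the mean of a gene's probes (0.0548) and with the replicate block (0.0605). Blood-testis barrier junction genes lost theirs with spike-in scaling (0.0573) and gene-median centring (0.0524).

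With an estimated correlation the adjusted p was 0.429 for apoptosis, complement, cytokines and chemokines, elongating spermatids, endothelial cells, extracellular matrix, Leydig cell markers, lipid-laden macrophages, macrophages, oestrogen-responsive genes, round spermatids and steroidogenic enzymes. It was 0.527 for blood-testis barrier junction genes and Sertoli cell markers, 0.593 for interferon-stimulated genes and sterol biosynthesis, 0.552 for meiotic spermatocytes and 0.502 for MHC class II presentation.

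Leaving out each array in turn, genes lower ran from 3817 to 5452 and Cyp19a1 from −0.48 to −0.19. The adjusted p ran from 0.0300 to 0.0951 for apoptosis, 0.0148 to 0.0647 for blood-testis barrier junction genes, 0.631 to 0.995 for epididymal epithelium, 0.510 to 0.911 for erythroid cells and 0.0465 to 0.428 for lymphocytes. Star, not called, ran from −1.02 to 0.0111, its value without AROM+ replicate 3. The replicate block called 3132 genes higher and 4605 lower, of which 3064 and 4467 are shared with the main result. With it Bax, Cstdc2, Ddx4, H2-Eb1, Ifit3 and Spam1 lost their call and Hbb-bt gained one (adjusted p = 0.0373). Deviations from the group mean correlated between same-numbered arrays at 0.0154, −0.236 and 0.00489, so the numbers were not used as pairs.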

Other observations

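The genes and windows below, and the tests of them, were chosen only after the results were seen. Among genes on no list, the seminal vesicle secretion genes Svs5 and Svs6 were at 3.18 and 4.59, and Svs4 was at −1.004. Lyve1 was at 5.42, and its probe was well above background on 1 of the 3 WT arrays. Around Hsd3b2 on chromosome 3, Hsd3b4 was at −1.44 and Hsd3b5, seen in WT only, at least 1.37-fold lower. Hsd3b7, encoded elsewhere, was at 1.17, and Hsd3b6 at 0.42 (adjusted p = 0.196). All of these but Hsd3b6 passed the limma threshold.

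In 2 Mb windows (1334, mm9), the window of chromosome 1 from 174 to 176 Mb, which holds interferon-inducible Ifi200 family genes, had the smallest p for features changed by at least 2 log2: 12 of 49, with 0.788 expected (adjusted p = 2.12e-08). At this limit the windows of chromosome 6 from 122 to 124 Mb (7 of 37, adjusted p = 0.00125), chromosome 11 from 82 to 84 Mb (6 of 45, adjusted p = 0.0366) and chromosome 3 from 98 to 100 Mb, with the Hsd3b genes (4 of 17, adjusted p = 0.0449), also passed. The window of chromosome 17 from 34 to 36 Mb passed at limits of 1 and 1.5 log2 (adjusted p = 0.00577 and 0.0070) and not at 2 (adjusted p = 0.373). The neighbouring window from 36 to 38 Mb passed at 1 log2 (adjusted p = 0.00577). The binomial test of windows takes features as independent. Some of the 12 features on chromosome 1 are overlapping stretches of the same locus, and windows such as that of Hsd3b hold related genes. These p-values therefore do not measure a regional effect.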
